A study of Homo sapiens with 11 samples.

How the data were processed

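Chromatin accessibility was measured by ATAC-seq (transposase-accessible chromatin sequencing) in MV4-11, a human acute myeloid leukaemia line that carries the MLL-AF4 fusion and that the labels list as a macrophage. The cells carried either a guide named gNT in the labels or a guide against RNF4, called gNT and gRNF4 cells here, and were kept for 7 days in medium with vehicle (DMSO) or with 100 nM GSK3685032, an inhibitor selective for the maintenance DNA methyltransferase DNMT1. RNF4 is a ubiquitin ligase that recognises proteins carrying SUMO chains. Groups were taken from the sample titles, with which the sample descriptions matched. The genotype tag in the labels follows the treatment rather than the guide (inhibitor-treated gNT libraries carry the knockout tag and vehicle-treated gRNF4 libraries the wild-type tag), so it was not used. The 11 libraries comprised 2 of gNT cells with vehicle (replicates 2 and 3) and 3 each of gNT cells with inhibitor, gRNF4 cells with vehicle and gRNF4 cells with inhibitor. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

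The authors deposited 1 table of raw read counts over 89162 peaks common to all libraries, in the column layout of featureCounts per the file headers. Per the submitters' processing notes, the tools were Trim Galore 0.4.4, Bowtie2 2.3.4.1, SAMtools, Picard 2.23.8, Genrich 0.6.0 and featureCounts, and the genome build was GRCh38.p13. Their roles and parameters, the handling of duplicate and mitochondrial reads, any shift of reads for the transposase and the way peaks were merged across libraries are not given in the sources used here. A further 1 column of counts matched no sample of the labels and was not used. The labels list no replicate 1 of gNT cells with vehicle, and whether that column belongs to it is not known, so the gNT effect and the interaction rest on 2 vehicle libraries of gNT cells. 8 peaks start at 0 in the deposited table, so starts were read as counting from 0 and are given counting from 1. Every peak held at least 73 counts in gRNF4 inhibitor replicate 3, and at least 19.6 counts per 100 bp there, whereas the lowest count was 0 in each of the other libraries. A peak seen only in other libraries could therefore be missing from the table, and no statement is made here about such regions. Counts that vary with the efficiency of transposition, with copy number or with the number of cells cannot be separated from accessibility in such a table.

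Total counts in peaks ran from 29621657 to 46233305 per library. Counts of replicate libraries differed by more than sampling noise in every pair of the same group (chi-square per degree of freedom from 3.187 to 17.71), so no library was treated as a duplicate. Peaks were filtered with filterByExpr of edgeR 4.0.16 (minimum count 10), which removed 11 and left 89151. Library sizes were scaled with TMM, and 1 quasi-likelihood fit (glmQLFit, glmQLFTest) with a mean for each of the 4 groups was made over all 11 libraries, so that the group of 2 shared the estimate of the spread. R 4.3.3 and limma 3.58.1 were used. The comparisons were inhibitor against vehicle in gNT cells and in gRNF4 cells, gRNF4 against gNT under vehicle and under inhibitor, the difference between both inhibitor effects (the interaction), and their mean weighted 4/9 for gNT and 5/9 for gRNF4 cells by the inverse of their variances. A peak was called at a Benjamini-Hochberg adjusted p under 0.05. Errors of log2 fold changes are standard errors derived from the F statistic, levels are CPM after TMM scaling with SD over libraries, and log2 CPM used a prior count of 2.

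The gene table (RefSeq, GRCh38.p14) gives the extent of each gene without strand, and served only to name neighbouring genes. Of 20037 protein-coding genes, 58.8% had a peak within 1 kb of an end, against 22.3% and 21.7% after moving all genes by 100000 bp either way. A gene-end peak lies within 1 kb of either end of a protein-coding or lncRNA gene, and which end is the transcription start is unknown. Other peaks were classed as within a gene, intergenic, or on a contig outside chromosomes 1 to 22, X and Y. No genome sequence was used, so CpG density, GC content, motifs, and exons against introns were not analysed here. Regions were named by a fixed rule: adjusted p under 0.05, a mean of at least 1 CPM, every library of one group beyond every library of the other (not required for the interaction), and the largest absolute log2 fold change, with at most 1 peak per gene. It took 10 regions per direction for each inhibitor effect and 5 per direction for the other comparisons. A region carries the name of the protein-coding gene with the nearest end within 50 kb, and its coordinates otherwise. It is said to lie within the named gene only where it overlaps that gene's extent, and beside it otherwise, where it may lie inside another gene. Chromosome Y was left out.

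Members of 15 gene lists were looked up at the gene-end peak with the highest mean count, and up to 4 per list were named by adjusted p. Members named beyond these 4, where few were called in a direction, were chosen after their values were seen. The values of some members are not reported here. Lists were compared with the other gene-end peaks by camera with a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over 75 tests. Of the calls with the preset correlation, 14 of 75, 0 held with an estimated correlation. For the monocyte and lymphoid lists the estimated correlation was negative, so a higher correlation between genes did not end those calls. Shares of called peaks by place were compared with peaks that were not called by Fisher's exact test, two-sided. Peaks are not independent, so those p-values describe these calls. For the set of peaks called in the weighted mean effect, the difference between inhibitor effects was tested on each library's mean log2 CPM with an exact two-sided permutation of the guides within each treatment (200 arrangements, smallest p 0.005). The test, comparisons, lists, naming rule and most alternatives were fixed before the data were examined. The naming rule, the lists and the classes of place had been set on transcription starts. Either gene end was used instead, because the gene table gives no strand.

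The fit was tested on simulated data with the real means and library sizes and 200 changed peaks among 89151. For inhibitor against vehicle in gNT cells it recovered 5 of 67 peaks changed 1.5-fold, 49 of 67 changed 2-fold and 66 of 66 changed 4-fold, with 8 false calls. For gRNF4 cells it recovered 12 of 67, 52 of 67 and 66 of 66, with 18 false calls. In both comparisons the share of false calls was above the level that the adjusted p threshold allows, and more so in gRNF4 cells. In the real data 45.5% of peaks were called in gNT and 6% in gRNF4 cells, far more than the share changed in the simulation. The cutoff set by the adjustment depends on that share, so the recovery need not hold for the real data. The alternatives tried were library-size scaling, median-of-ratios size factors, scaling from gene-end peaks, smooth offsets on abundance (loess span 0.3) with and without place classes, no filter and stricter filters, an adjusted p of 0.01, fits to the compared groups alone, DESeq2 1.42.0, the replicate number as a block, thinning to the lowest total, subsets of peaks, and each library left out in turn. Scaling from gene-end peaks and offsets within place classes take out a shift shared by gene-end peaks. A gene-end call lost there can thus be lost by design. Alternatives that needed the genome sequence or the strand of genes were not run.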

Results

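The series measured chromatin accessibility by ATAC-seq in MV4-11 leukaemia cells after 7 days, to ask how a guide against RNF4 alters the accessibility changes made by the DNMT1 inhibitor GSK3685032 at 100 nM. The 11 libraries fell into 4 groups: gNT cells with vehicle (n = 2), gNT cells with inhibitor (n = 3), gRNF4 cells with vehicle (n = 3) and gRNF4 cells with inhibitor (n = 3). Total counts in peaks lay between 43433005 and 45138079 in vehicle-treated and between 35252613 and 44407283 in inhibitor-treated gNT cells. They lay between 31289734 and 43419678 in vehicle-treated and between 29621657 and 46233305 in inhibitor-treated gRNF4 cells. On the first principal component, with 63% of the variance of log2 CPM, the inhibitor-treated gNT libraries lay between 112.6 and 138.6, all vehicle libraries between -74.1 and -52.1, and the inhibitor-treated gRNF4 libraries at -2.3, -10 and -35.9. The next component, with 12% of the variance, was led by gRNF4 inhibitor replicate 3 at -88.1 and gNT vehicle replicate 3 at 65.7, which were from groups of different guide and treatment.

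**Figure D1:**
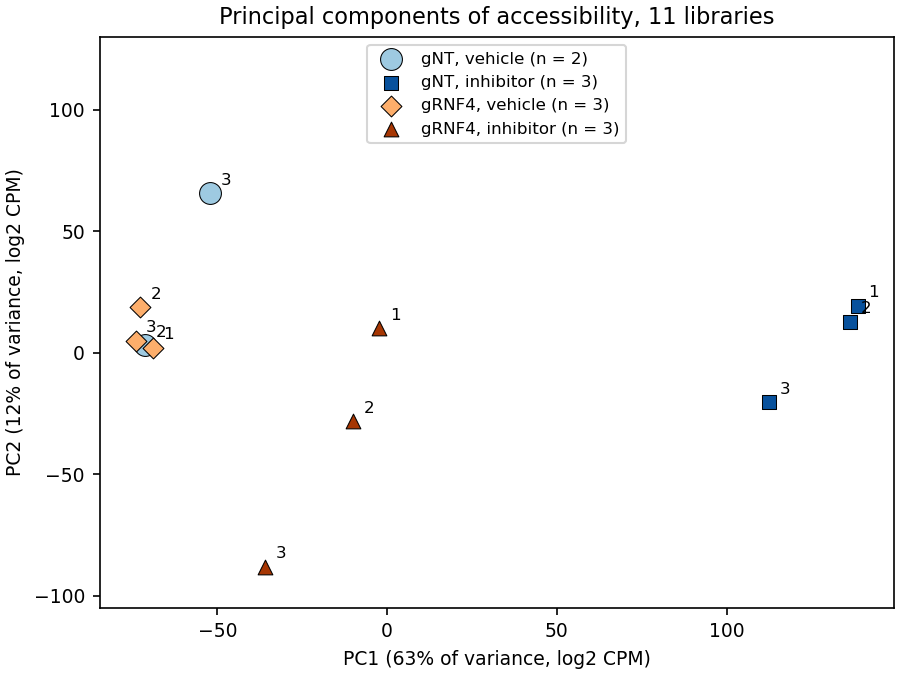
Principal components of log2 CPM over 89151 peaks, 1 point per library labelled with its replicate number, with colour and shape for the 4 groups. The vehicle libraries of both guides overlap on the first component, and the inhibitor-treated gRNF4 libraries lie between them and the inhibitor-treated gNT libraries.

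At RNF4, the targeted gene, the main gene-end peak (chromosome 4, 2468819 to 2469315, GRCh38) held 20.04 ± 2.09 CPM (SD, n = 2) in vehicle-treated and 27.7 ± 2.27 CPM (n = 3) in inhibitor-treated gNT cells. In gRNF4 cells it held 20.23 ± 1.33 CPM with vehicle and 20.33 ± 2.79 CPM with inhibitor (n = 3 each). The guide did not measurably alter it under vehicle (log2 fold change 0.01 ± 0.13, adjusted p = 0.994 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The inhibitor raised it in gNT cells (0.47 ± 0.14, adjusted p = 0.0114 by the same edgeR test), and this call ended with scaling from gene-end peaks (0.25, adjusted p = 0.165) and with offsets within place classes (0.19, adjusted p = 0.136). In gRNF4 cells the value was 0.01 ± 0.12 (adjusted p = 0.988 by edgeR), and the difference between both effects was -0.46 ± 0.18 (adjusted p = 0.0979 by edgeR). Under inhibitor it was lower in gRNF4 than in gNT cells (-0.45 ± 0.12, adjusted p = 0.00863 by edgeR), which also ended with scaling from gene-end peaks (-0.23, adjusted p = 0.145) and with offsets within place classes (-0.16, adjusted p = 0.18). Both settings take out the shift shared by gene-end peaks, so they show only whether this peak moved beyond it. Another gene-end peak of RNF4, at 2469707 to 2469937, was lower in inhibitor-treated gNT cells (-0.72 ± 0.25, adjusted p = 0.0293 by edgeR). So were 3 peaks inside the gene, at 2484190 to 2484556 (-1.10 ± 0.26, adjusted p = 0.00311), 2484730 to 2485609 (-0.47 ± 0.11, adjusted p = 0.00305) and 2497441 to 2498317 (-0.37 ± 0.12, adjusted p = 0.0185). The last call ended with offsets within place classes (-0.20, adjusted p = 0.105 by edgeR). Under inhibitor these 3 were higher in gRNF4 than in gNT cells (1.06 ± 0.24, 0.39 ± 0.10 and 0.41 ± 0.11, adjusted p = 0.00304, 0.00609 and 0.00707 by edgeR). A guide that cuts a coding sequence need not change accessibility, so these peaks check neither the labels nor the depletion. At DNMT1, the inhibitor's target, the gene-end peak on chromosome 19 (10194555 to 10195372) did not pass the test in gNT cells (0.51 ± 0.26, adjusted p = 0.126 by edgeR), but did without gRNF4 inhibitor replicate 3 (adjusted p = 0.0311). Of the peaks within DNMT1, 1 (10137223 to 10139623) fell from 15.65 ± 0.02 to 10.24 ± 0.28 CPM (-0.61 ± 0.13, adjusted p = 0.00136 by edgeR). Those at 10144944 to 10145326 (-0.71 ± 0.19, adjusted p = 0.0065) and 10157722 to 10158434 (-0.56 ± 0.19, adjusted p = 0.0265) fell as well, and the last call ended with thinned libraries (-0.42, adjusted p = 0.113). The peak at 10189644 to 10190535 did not pass (0.32 ± 0.13, adjusted p = 0.0509 by edgeR), but passed in 4 of 7 settings with positive values, among them that without gRNF4 inhibitor replicate 3 (adjusted p = 0.0443).

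The first comparison asked what the inhibitor did in gNT cells. The largest rise was at an intergenic region beside JADE2, a PHD-finger subunit of a histone acetyltransferase complex (chromosome 5, 134482946 to 134483499), which went from 0.96 ± 0.37 CPM (n = 2) to 90.04 ± 10.39 CPM (n = 3). This was a log2 fold change of 6.56 ± 0.28 (adjusted p = 3.93e-09, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). A region beside CD300LG, an endothelial receptor of the CD300 family (chromosome 17, 43842310 to 43842916), rose by 6.54 ± 0.32. A region within DNAAF5, an assembly factor of axonemal dynein (chromosome 7, 768094 to 768473), rose by 6.45 ± 0.28. Peaks within ADPRHL1 (chromosome 13, 113448955 to 113449685) and the succinate dehydrogenase gene SDHA (chromosome 5, 261062 to 261738) rose by 5.55 ± 0.26 and 5.51 ± 0.28. A peak beside the lysophospholipid acyltransferase gene LPCAT1 (chromosome 5, 1569891 to 1570454) rose by 5.44 ± 0.20. The gene-end peak of ZNF772, a KRAB zinc finger gene (chromosome 19, 57477503 to 57477811), rose from 0.65 ± 0.15 to 26.87 ± 0.99 CPM, or 41.1-fold. A region beside DHRSX (chromosome X, 2185729 to 2186366) rose by 5.26 ± 0.30. It lies in the pseudoautosomal part, whose reads can come from either sex chromosome. A region beside LY86, which encodes a partner of the receptor CD180 (chromosome 6, 6686908 to 6687317), rose by 5.10 ± 0.33. The last of the 10, at chromosome X, 131741114 to 131741550, rose by 5.35 ± 0.30.

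The largest fall in gNT cells was beside ICOSLG, which encodes a T-cell costimulatory ligand (chromosome 21, 44182197 to 44182492), from 5.92 ± 0.24 to 0.46 ± 0.11 CPM. This was a log2 fold change of -3.66 ± 0.24 (adjusted p = 9.18e-08 by edgeR). Regions beside the serine protease gene PRSS38 (chromosome 1, 227869517 to 227870325) and the transporter gene SLC38A11 (chromosome 2, 164890694 to 164890909) changed by -3.45 ± 0.22 and -3.10 ± 0.25. A region within the malic enzyme gene ME3 (chromosome 11, 86473141 to 86473489) and 1 beside the intraflagellar transport gene IFT70A (chromosome 2, 177584135 to 177584355) each changed by -3.03. A region beside SPDYE17 (chromosome 7, 77020709 to 77021069) changed by -3.09 ± 0.20, which is uncertain because reads of that multicopy family can be split between copies. Further falls were at chromosome 16, 79844997 to 79845278 (-3.54 ± 0.23), and chromosome 22, 48045393 to 48045765 (-3.52 ± 0.18). The remaining ones were at chromosome X, 140744148 to 140744444 (-3.28 ± 0.19), and chromosome 6, 79605108 to 79605378 (-2.98 ± 0.20). By the naming rule, all 3 inhibitor libraries lay beyond both vehicle libraries in each of these 20 regions. Over all 89151 peaks, 19890 were higher and 20717 lower in inhibitor-treated gNT cells (45.5% of peaks; adjusted p under 0.05 by edgeR). Of these, 5214 higher and 5149 lower ones changed more than 2-fold. The balance depended on the scaling: 49% of the calls were higher with TMM, 36.7% with library-size scaling and 28% with scaling from gene-end peaks. The latter 2 moved the median log2 fold change of all peaks from 0.008 to -0.116 and -0.208. The higher share was 50.1% with median-of-ratios size factors, 49.5% with offsets on abundance, 50% with offsets within place classes and 50.5% with DESeq2.

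**Figure D2:**
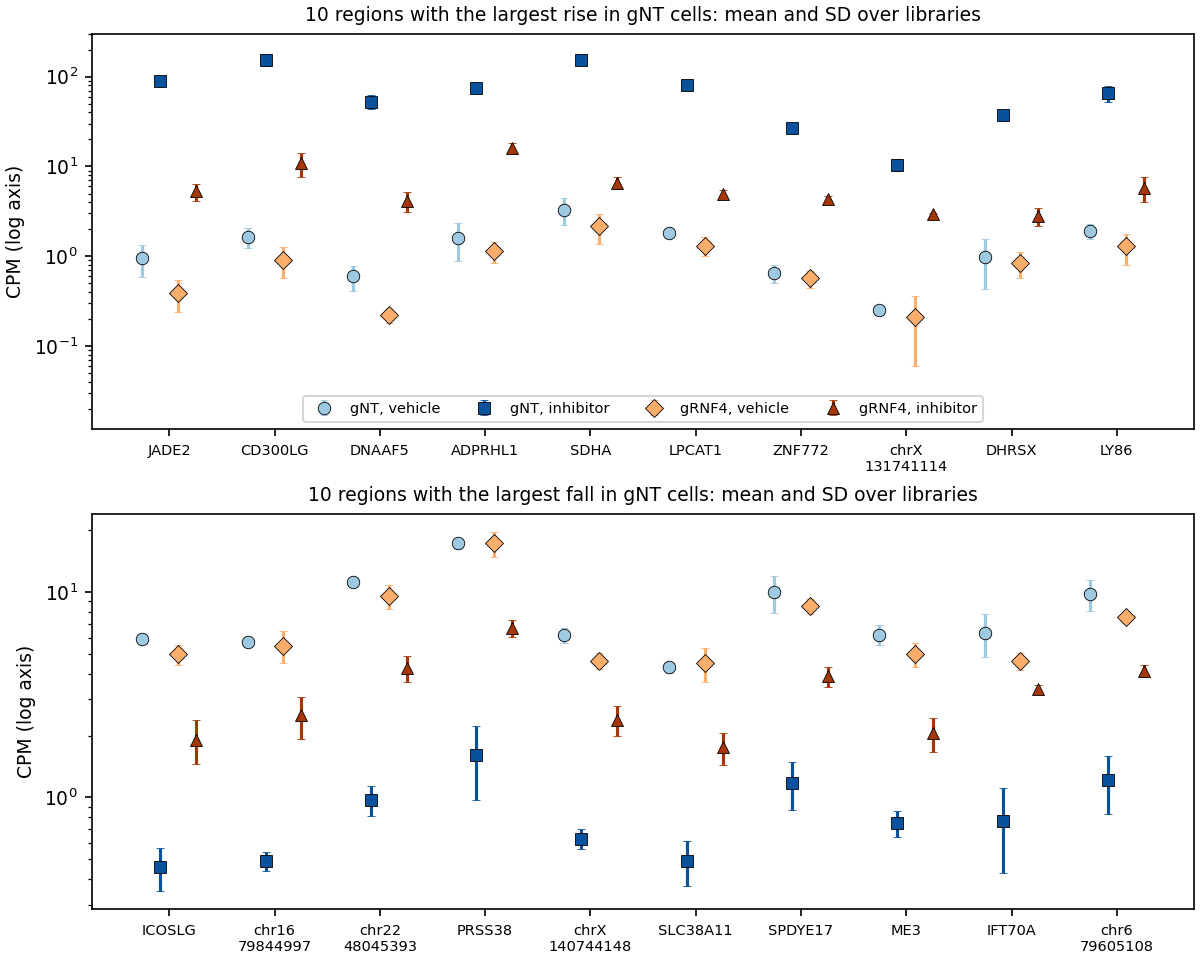
Mean CPM with SD over libraries (log axis) in the 4 groups for the 10 regions with the largest rise (top) and the 10 with the largest fall (bottom) in inhibitor-treated gNT cells, named by gene or by chromosome and start. The JADE2 region stood at 90.04 CPM in inhibitor-treated gNT cells and 5.3 CPM in inhibitor-treated gRNF4 cells, and the ICOSLG region at 0.46 and 1.91 CPM.

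By place, 29.8% of the 18058 gene-end peaks were higher and 13.6% lower in inhibitor-treated gNT cells, against 20% higher and 26% lower among the 41582 peaks within genes, and 20.5% and 26.1% among 26547 intergenic peaks. The odds ratio of gene-end peaks among higher peaks, against peaks that were not called, was 1.39 (95% interval 1.34 to 1.45, adjusted p = 1.56e-63, Fisher's exact test, two-sided). Among lower peaks it was 0.50 (0.48 to 0.53, adjusted p = 4.43e-193 by the same test). Chromosome 19, which holds most KRAB zinc finger clusters, had the highest median of any chromosome (0.21, with 0.33 at gene-end and 0.16 at other peaks). The medians of the others lay between -0.06 and 0.07. The share of counts in gene-end peaks moved with the groups: 37.2 ± 2.3% (n = 2) in gNT vehicle, 42.5 ± 2.2% in gNT inhibitor, 36.4 ± 0.5% in gRNF4 vehicle and 37.6 ± 3.1% in gRNF4 inhibitor libraries (n = 3 each).

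Gene lists were read at gene-end peaks, whose median over all genes was itself 0.27 in inhibitor-treated gNT cells. Because scaling from gene-end peaks and offsets within place classes take out a shift shared by these peaks, fewer rises are called there by design. Of 42 KRAB zinc finger genes with a peak, which encode DNA-binding repressors, 28 rose and 0 fell in gNT cells (30 and 0 adjusted over the list alone). Among them were ZNF772 (5.36 ± 0.19), ZNF225 (1.09 ± 0.11), ZNF850 (0.94 ± 0.11) and ZNF766 (0.85 ± 0.15). Fewer calls came with scaling from gene-end peaks (11 higher and 0 lower) and with offsets within place classes (11 and 3). By camera with the preset correlation, the list stood above other gene-end peaks (adjusted p = 0.00501), but not with an estimated one (adjusted p = 0.436 with an estimated correlation). Of 26 SUMO pathway genes, 11 rose and 0 fell (11 and 0 adjusted over the list alone, 8 and 1 with scaling from gene-end peaks). USP7 (4.22 ± 0.17), a deubiquitinase that acts on DNMT1 and MDM2, SLF2 (0.89 ± 0.15) and the SUMO ligase PIAS1 (1.30 ± 0.24) were among them. The camera call of that list (adjusted p = 0.0382) was lost as well (adjusted p = 0.851 with an estimated correlation). Of 25 p53 target genes, 13 rose and 0 fell (14 and 0 adjusted over the list alone, 9 and 2 with scaling from gene-end peaks). Among them were FDXR (0.95 ± 0.11), the DNA damage sensor XPC (1.07 ± 0.16) and SESN2 (0.83 ± 0.16). Of 27 genes of the DNA methylation machinery, 10 rose and CDCA7 (-0.40 ± 0.14) fell (10 and 1 adjusted over the list alone, 7 and 2 with scaling from gene-end peaks). Beside USP7, which both lists hold, CBX3 (0.66 ± 0.13), ZBTB4 (0.65 ± 0.13) and the H3K9 methyltransferase SETDB1 (0.53 ± 0.12) led the rises. Camera did not call these last 2 lists.

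The germline and imprinted lists, which hold genes that DNA methylation helps to regulate, were read next. Only 8 of 49 germline and cancer-testis genes had a gene-end peak, and MAGEB2 (1.18 ± 0.14) and PRAME (0.96 ± 0.18) rose in gNT cells (2 higher and 0 lower, also adjusted over the list alone). Of 40 imprinted genes, 16 had a gene-end peak. Among these 16, 5 rose and 0 fell (5 and 0 adjusted over the list alone, 4 and 1 with scaling from gene-end peaks, 8 and 0 without gRNF4 inhibitor replicate 3). These were MCTS2 (1.08 ± 0.16), INPP5F (1.31 ± 0.21), BLCAP (0.67 ± 0.12), IGF2R (0.70 ± 0.14) and PHLDA2 (0.52 ± 0.18). The list medians were 0.23 for germline and 0.36 for imprinted genes, against 0.27 over all genes. Of all gene-end peaks 29.8% were higher, a share near those of both lists. Neither list was called by camera with the preset correlation (adjusted p = 0.499 for germline and 0.345 for imprinted genes). Interferon-stimulated genes divided, with 7 of 35 higher and 5 lower in gNT cells (7 and 5 adjusted over the list alone). By adjusted p, IRF9 (0.89 ± 0.11), OAS2 (-0.87 ± 0.13), STAT2 (0.78 ± 0.15) and IFIT1 (-0.62 ± 0.13) led the list. Scaling from gene-end peaks turned that list to 5 higher and 10 lower, and offsets within place classes to 5 and 12. Of 17 nucleic acid sensing genes, 2 rose and 4 fell (2 and 4 adjusted over the list alone, 1 and 4 with scaling from gene-end peaks). TLR9 (-1.04 ± 0.12), TLR7 (-1.12 ± 0.18), IKBKE (-0.34 ± 0.10) and STING1 (-0.34 ± 0.12) fell, and MYD88 (0.71 ± 0.14) and IRF3 (0.36 ± 0.13) rose. All named changes had an adjusted p under 0.05 over all peaks by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

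Lineage genes moved in both directions in gNT cells. Of 31 monocyte and macrophage genes, 7 rose and 8 fell (7 and 9 adjusted over the list alone, 4 and 12 with scaling from gene-end peaks). The scavenger receptor gene MARCO (-1.46 ± 0.14), the Fc receptor chain gene FCER1G (-1.02 ± 0.19) and CSF1R (-0.73 ± 0.14) fell, and NCF1 (1.21 ± 0.18), whose reads can be shared with near-identical pseudogenes, rose. Of 17 lymphoid genes, 3 rose and 7 fell (3 and 7 adjusted over the list alone). The falls were led by the granule gene NKG7 (-1.23 ± 0.12), the surrogate light chain gene IGLL1 (-2.27 ± 0.23), CD79A (-0.72 ± 0.11) and CD3E (-0.73 ± 0.12). The 3 that rose were CD8A (0.52 ± 0.11), GNLY (0.52 ± 0.14) and CD79B (0.66 ± 0.19), and with scaling from gene-end peaks 0 rose and 7 fell. Both lists lay below other gene-end peaks by camera (adjusted p = 0.0386 for monocyte and 0.00712 for lymphoid genes), and neither call held (adjusted p = 0.192 and 0.143 with an estimated correlation). Their estimated correlations were -0.02 and -0.021, below the preset 0.01, so a higher correlation between genes was not what ended these calls. Of 15 granulocyte and granule genes, FPR1 (-0.84 ± 0.13), CXCR2 (-0.42 ± 0.14) and CTSG (-0.30 ± 0.10) fell and no other member passed (0 higher and 1 lower adjusted over the list alone, 1 and 4 with scaling from gene-end peaks, 0 and 7 with offsets within place classes). Of 22 stem cell and MLL-fusion genes, 5 rose and 3 fell (3 and 3 adjusted over the list alone). The repressor gene GFI1B (1.34 ± 0.17), MBNL1 (0.87 ± 0.17), BCL2 (0.42 ± 0.16) and MYB (0.37 ± 0.15) were among those that rose. HOXA13 (-0.44 ± 0.12), LMO2 (-0.37 ± 0.13) and MYC (-0.36 ± 0.12) fell. With scaling from gene-end peaks that list had 2 higher and 6 lower, and with offsets within place classes 2 and 8.

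Of 13 erythroid and megakaryocyte genes, 2 rose and 3 fell in gNT cells (2 and 3 adjusted over the list alone, 2 and 4 with scaling from gene-end peaks). KLF1 (0.99 ± 0.16) and GP9 (1.02 ± 0.22) rose, and ITGA2B (-0.56 ± 0.13), HBD (-0.44 ± 0.14) and TAL1 (-0.40 ± 0.14) fell. Of 28 housekeeping genes, 7 rose and 3 fell (7 and 2 adjusted over the list alone, 5 and 4 with scaling from gene-end peaks, 4 and 6 with offsets within place classes, 14 and 3 without gRNF4 inhibitor replicate 3). HSP90AB1 (-1.06 ± 0.14), ACTB (-1.19 ± 0.21) and REEP5 (-0.34 ± 0.13) were lower, and EEF1A1 (0.56 ± 0.11) and POLR2A (0.65 ± 0.13) were among the higher ones. Of 9 fibroblast and epithelial genes, COL1A2 (0.77 ± 0.17), COL1A1 (0.71 ± 0.16) and KRT8 (0.43 ± 0.12) rose, and CLDN7 (-0.71 ± 0.16) and PDGFRB (-0.74 ± 0.19) fell (3 and 2 adjusted over the list alone, 2 and 2 with scaling from gene-end peaks). A peak within 1 kb of 2 genes counts for both, as at ZBTB4 and POLR2A. Of the 144 list entries called in gNT cells by edgeR (adjusted p under 0.05), all 144 had the same sign and 100 kept their call with scaling from gene-end peaks. Without gRNF4 inhibitor replicate 3, 144 kept it. That library is in neither group of this comparison and acts mainly through the shared spread, so this is no check of these calls.

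**Figure D3:**
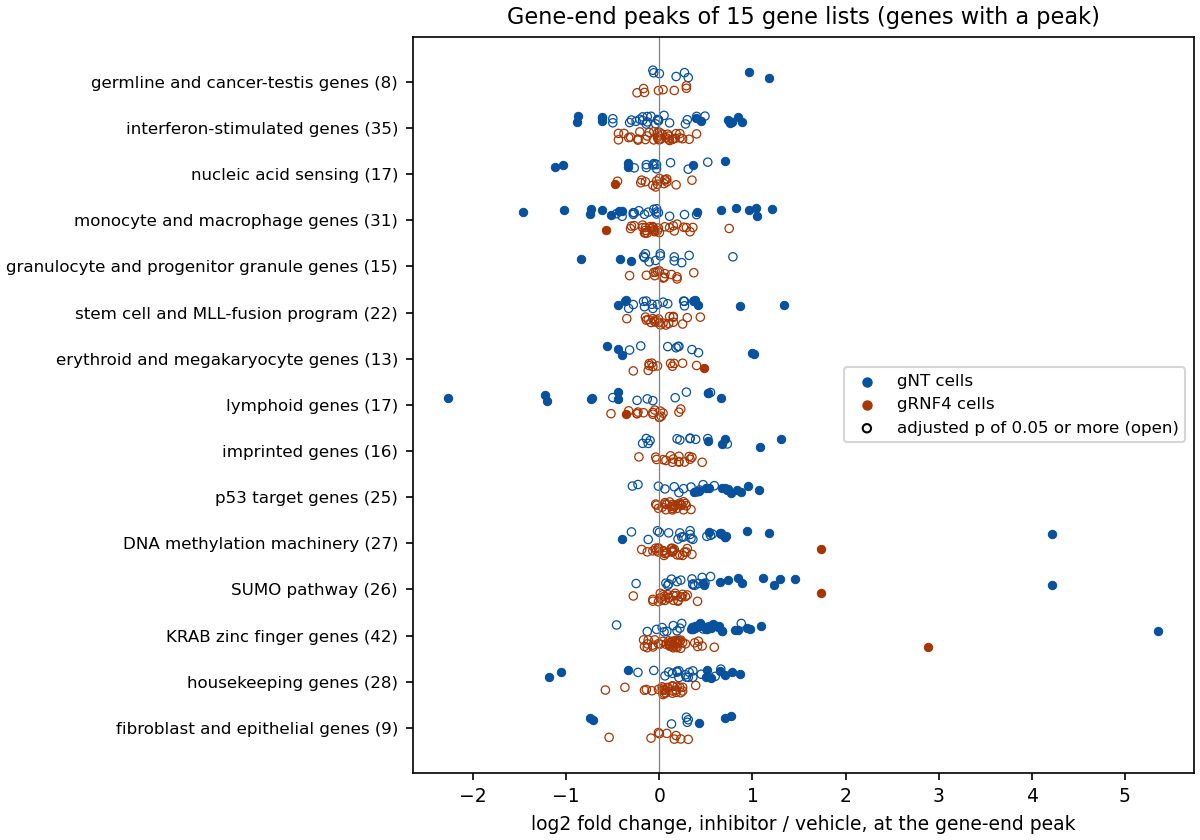
Log2 fold change of inhibitor against vehicle at the gene-end peaks of 15 gene lists, in gNT cells (blue) and gRNF4 cells (brown), with 1 point per gene and filled points for adjusted p under 0.05. Of 42 KRAB zinc finger genes, 28 passed the test in gNT cells and 1 in gRNF4 cells, and all of these were higher.

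The inhibitor was next compared with vehicle in gRNF4 cells. Of the 10 regions with the largest rises there, DNAAF5, ADPRHL1, CD300LG and that at chromosome X were also among the 10 of gNT cells. JADE2 was named in both at neighbouring peaks. The peak named in gRNF4 cells rose by 6.38 in gNT cells, and that named in gNT cells by 3.7 in gRNF4 cells. The DNAAF5 region rose from 0.22 ± 0.04 to 4.13 ± 1.04 CPM (n = 3 each). This was a log2 fold change of 4.19 ± 0.29 (adjusted p = 5.95e-06, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Regions beside JADE2 (chromosome 5, 134483743 to 134484172) and within ADPRHL1 rose by 3.91 ± 0.27 and 3.78 ± 0.22, and that beside CD300LG by 3.59 ± 0.27. A region beside the replicative helicase gene MCM5 (chromosome 22, 35491385 to 35492071) rose by 3.61 ± 0.20, from 1.79 ± 0.22 to 21.84 ± 4.73 CPM, and 1 beside RSPH14 (chromosome 22, 23197932 to 23198213) by 3.06 ± 0.24. A region within the transglutaminase gene TGM3 (chromosome 20, 2302503 to 2302690) rose by 3.08 ± 0.27, against 3.11 in gNT cells. The remaining rises were at chromosome 8, 106060428 to 106060718 (3.92 ± 0.32), chromosome X, 131741114 to 131741550 (3.67 ± 0.29), and chromosome 2, 41941913 to 41942132 (3.04 ± 0.29). The largest fall was within TSPEAR (chromosome 21, 44517306 to 44517663), at -1.56 ± 0.17, from 9.51 ± 0.75 to 3.20 ± 0.63 CPM. ICOSLG (-1.38 ± 0.19), SLC38A11 (-1.37 ± 0.19) and PRSS38 (-1.37 ± 0.18) followed. A region within SLC15A5 (chromosome 12, 16198931 to 16199320) changed by -1.37 ± 0.12, and 1 within the actin filament protein gene AFAP1 (chromosome 4, 7798119 to 7798557) by -1.32 ± 0.16. Regions at ME3 (-1.27 ± 0.17), LOC107987042 (chromosome 9, 711253 to 711546; -1.27 ± 0.17), chromosome 2, 59414092 to 59414548 (-1.35 ± 0.14), and chromosome 9, 100689730 to 100689952 (-1.27 ± 0.17), completed the 10.

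Over all peaks, 2980 were higher and 2403 lower in inhibitor-treated gRNF4 cells (6% of peaks), 596 and 83 of them by more than 2-fold. Because every peak held at least 73 counts in gRNF4 inhibitor replicate 3, regions with strong falls in that group may be missing. The excess of large rises can therefore not be read as a property of the cells. Few list genes passed the edgeR test: ZNF772 (2.89) and USP7 (1.74) were higher, and MARCO (-0.57) and TLR9 (-0.48) lower. KLF1 (0.48) and CD79A (-0.36) also passed, but no erythroid gene was called higher in any of 7 other settings, gRNF4 inhibitor replicate 3 left out among them. No lymphoid gene was called lower in 5 of these 7, among them library-size scaling and scaling from gene-end peaks. KRAB zinc finger genes had 1 call among 42, with a camera call (adjusted p = 0.00501) that was lost (adjusted p = 0.436 with an estimated correlation). Lymphoid genes had 1 call among 17 (adjusted p = 0.0294 by camera, 0.192 with an estimated correlation). SUMO pathway genes and DNA methylation genes each had the 1 call of USP7. No p53 target, interferon-stimulated, germline or imprinted gene passed the edgeR test, over all peaks or adjusted over the list alone. Without gRNF4 inhibitor replicate 3, and also with offsets within place classes, 1 imprinted gene was called higher. Gene-end peaks were under-represented among lower peaks (odds ratio 0.41, adjusted p = 2.06e-45, Fisher's exact test, two-sided) and among higher peaks (0.49, adjusted p = 5.28e-41). The latter ended without gRNF4 inhibitor replicate 3 (0.92, p = 0.142 by Fisher's exact test, two-sided). The counts were 1519 higher and 1066 lower without gRNF4 vehicle replicate 1, and 1282 and 743 without gRNF4 vehicle replicate 2. They were 1580 and 1304 without gRNF4 vehicle replicate 3, and 1635 and 882 without gRNF4 inhibitor replicate 2. The share of higher calls was 55.4%, and 65% without gRNF4 inhibitor replicate 2. With scaling from gene-end peaks 1147 were higher and 1177 lower, a higher share of 49.4%.

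The inhibitor effects of both cell populations were set against each other, with no library in common. Of the peaks higher in gRNF4 cells, 2371 (79.6%) were also higher in gNT cells, where 665 would be shared by independent lists, and of the lower ones 2134 (88.8%), against 558. Opposite calls were rare: 26 peaks were higher in gRNF4 and lower in gNT cells, and 23 the reverse. Across peaks, which are not independent replicates, Pearson's r between both effects was 0.634 and Spearman's rho 0.601. Peaks called higher in gNT cells had a median log2 fold change of 0.75 there and 0.21 in gRNF4 cells, where 84.5% had the same sign, and those called lower had -0.72 and -0.20 with 83.4%.

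**Figure D4:**
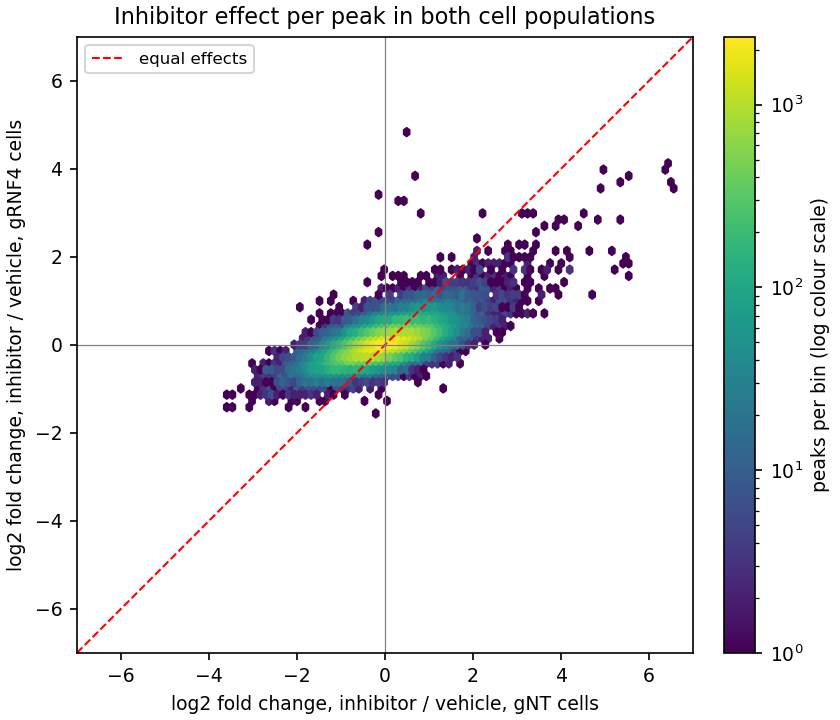
Log2 fold change of inhibitor against vehicle per peak in gNT cells (horizontal) and gRNF4 cells (vertical), with colour for the number of peaks per bin on a log scale and a dashed line for equal effects. Peaks with large effects in gNT cells lie between that line and the horizontal axis, with Pearson's r of 0.634.

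The interaction tested whether the inhibitor effect differed between gRNF4 and gNT cells. At SDHA the inhibitor effect in gRNF4 cells less that in gNT cells was -3.91 ± 0.34 log2 units (adjusted p = 5e-05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Its level rose from 3.31 ± 1.10 to 151.22 ± 15.37 CPM in gNT cells (n = 2 and 3) and from 2.18 ± 0.81 to 6.63 ± 1.0 CPM in gRNF4 cells (n = 3 each). LPCAT1 (-3.51 ± 0.25), DHRSX (-3.49 ± 0.41), LY86 (-2.96 ± 0.41) and CD300LG (-2.95 ± 0.40) followed. Among regions that fell in gNT cells, those beside GALM, which encodes galactose mutarotase (chromosome 2, 38738861 to 38739280; 2.82 ± 0.42), and IFT70A (2.57 ± 0.32) differed upward. So did regions at chromosome 5, 98031063 to 98031333 (2.57 ± 0.56), chromosome 5, 108054309 to 108054663 (2.45 ± 0.28), and chromosome 17, 2179628 to 2180081 (2.44 ± 0.27). The GALM region and that at 98031063 had low levels. In gRNF4 cells they went from 1.04 ± 0.13 and 0.73 ± 0.08 CPM to 1.89 ± 0.71 and 1.49 ± 0.53 CPM. In gNT cells they went from 2.06 and 1.44 CPM to 0.52 and 0.53 CPM. Neither rise in gRNF4 cells passed (adjusted p = 0.0715 and 0.103 by edgeR). The minimum count of every peak in gRNF4 inhibitor replicate 3 can weigh on such low levels. Without that library all 10 regions named for the interaction, both of these among them, kept their sign and call. The rises of both regions in gRNF4 cells were not looked at without it. TSPEAR and AFAP1 differed downward, with larger falls in gRNF4 cells (-1.40 ± 0.24, adjusted p = 0.00216, and -0.87 ± 0.24, adjusted p = 0.0246, by edgeR). At TGM3 no difference was detectable (-0.02 ± 0.55, adjusted p = 0.983). Called list genes included USP7 (-2.49), SLF2 (-0.69) and SUMO2 (-1.21) of the SUMO pathway, and ZNF772 (-2.47), ZNF225 (-0.94), ZNF850 (-0.75) and ZNF773 (-0.80) of the KRAB genes. FDXR (-0.81) and XPC (-0.88) were called among the p53 targets, and IGLL1 (1.75), NKG7 (0.91), GZMB (0.98) and CD8A (-0.70) among the lymphoid genes. Camera called the SUMO (adjusted p = 0.0324; 0.851 with an estimated correlation), KRAB (0.0294; adjusted p = 0.592 with an estimated correlation) and lymphoid lists (0.0181; adjusted p = 0.186 with an estimated correlation).

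Over all peaks the interaction was higher at 7680 and lower at 5769 by edgeR (adjusted p under 0.05), and 99.7% of the higher and 99.9% of the lower ones opposed the sign of the gNT effect. The effect was smaller in size in gRNF4 cells at 96.6% and 97.2% of them. The interaction contains the gNT effect with a minus sign, so all of these shares follow in part from the selection of peaks. Without gNT vehicle replicate 2 the counts were 4408 and 3166, and without gNT vehicle replicate 3 they were 4938 and 3613. The lower count was 3600 without gNT inhibitor replicate 1 and 3587 without gRNF4 vehicle replicate 1. The higher share was 57.1% with TMM, 73.4% with library-size scaling and 79.1% with scaling from gene-end peaks. It was 52.8% with median-of-ratios size factors, 53.3% with offsets on abundance, 52.4% with offsets within place classes and 51.8% with DESeq2. Over the 18302 peaks higher in the weighted mean effect, mean log2 CPM went from 2.38 ± 0.01 to 3.21 ± 0.03 in gNT cells (SD, n = 2 and 3) and from 2.36 ± 0.02 to 2.71 ± 0.02 in gRNF4 cells (n = 3 each). The effects differed by -0.48 ± 0.03 (SE). An exact two-sided permutation of the guides within treatment gave p = 0.09 among 200 arrangements, where 0.005 is the smallest possible. Over the 18534 lower peaks the means went from 3.06 ± 0.01 to 2.24 ± 0.04 and from 3.05 ± 0.01 to 2.75 ± 0.03, a difference of 0.52 ± 0.03 (p = 0.02 by the same exact permutation). Both p-values are coarse, because exchanging vehicle libraries between guides hardly moves the means and such arrangements come close to the real one. Their median differences per peak were -0.47 and 0.49. By the same exact permutation, p for the higher peaks was 0.025 without gNT vehicle replicate 2, and p for the lower peaks was 0.05 without gRNF4 vehicle replicate 1 or 3. With scaling from gene-end peaks, p by that test was 0.045 for the higher and 0.07 for the lower peaks, so which of both passed depended on the scaling.

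Under vehicle, gRNF4 and gNT cells were compared to ask what the guide did alone. The JADE2 region held 0.39 ± 0.15 CPM in gRNF4 cells (n = 3) and 0.96 ± 0.37 CPM in gNT cells (n = 2), ICOSLG 4.97 ± 0.55 and 5.92 ± 0.24 CPM, and ZNF772 0.57 ± 0.12 and 0.65 ± 0.15 CPM. 0 of 89151 peaks passed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (lowest adjusted p = 0.444), with 4844 peaks (5.4%) at an unadjusted p under 0.05. DESeq2 called 3 higher and 24 lower, and a fit to these 5 libraries alone 1 and 38. Scaling from gene-end peaks called 0 and 3, offsets within place classes 0 and 1, and the fit without gNT inhibitor replicate 2 called 0 and 2. Of the 15 lists, only monocyte and macrophage genes were called by camera (higher, median 0.06 against -0.06 at all gene-end peaks, adjusted p = 0.00501), and that call was lost (adjusted p = 0.143 with an estimated correlation).

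Under inhibitor, the guide separated the groups. The SDHA region at chromosome 5, 260292 to 260808, held 94.43 ± 13.77 CPM in gNT and 3.79 ± 0.60 CPM in gRNF4 cells (n = 3 each). This was a log2 fold change of -4.64 ± 0.22 (adjusted p = 2.6e-08, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). JADE2 (-4.09 ± 0.20), LPCAT1 (-4.01 ± 0.15), CD300LG (-3.83 ± 0.23) and DHRSX (-3.72 ± 0.23) were also lower in gRNF4 cells. A region beside TLR2, which encodes a receptor for bacterial lipoproteins (chromosome 4, 153731306 to 153731591), was higher by 2.44 ± 0.18, at 5.54 ± 0.23 against 1.02 ± 0.27 CPM, and 1 beside SEMA6D (chromosome 15, 47814063 to 47814318) by 2.29 ± 0.19. Regions at chromosome 17, 2179628 to 2180081 (2.55 ± 0.20), chromosome 16, 79844997 to 79845278 (2.36 ± 0.23), and chromosome X, 20418357 to 20418787 (2.3 ± 0.18), were higher as well. Of the lists, 14 of 26 SUMO pathway genes were lower and 1 higher (15 and 1 adjusted over the list alone), and 17 of 42 KRAB genes lower and 0 higher (16 and 0). Also lower were 10 of 27 DNA methylation genes with 0 higher (10 and 0), 10 of 28 housekeeping genes with 1 higher (10 and 1) and 9 of 25 p53 target genes with 1 higher (12 and 1). Of all gene-end peaks, 30.3% were lower, with a median of -0.21. The lists use only the peak with the highest count per gene, where the median over all genes was -0.26. Their background share may thus be higher than 30.3%. Of 31 monocyte and macrophage genes, 10 were higher and 5 lower (10 and 5). With scaling from gene-end peaks these were 10 lower and 1 higher for SUMO, 10 and 1 for KRAB, 6 and 3 for DNA methylation, 3 and 3 for housekeeping and 8 and 2 for p53 target genes, and 15 higher and 3 lower for monocyte and macrophage genes. Without gRNF4 inhibitor replicate 3, 9 SUMO pathway, 11 KRAB and 5 DNA methylation genes were lower. By camera the SUMO list was lower (adjusted p = 0.0181; 0.851 with an estimated correlation). The monocyte (adjusted p = 0.00501; 0.143 with an estimated correlation), lymphoid (adjusted p = 0.00738; 0.143 with an estimated correlation) and nucleic acid sensing lists (adjusted p = 0.0386; 0.436 with an estimated correlation) were higher than other gene-end peaks. In all, 18951 peaks were higher and 17421 lower in gRNF4 cells by edgeR. The higher share was 52.1% with TMM, 66.2% with library-size scaling and 76.8% with scaling from gene-end peaks, whose medians over all peaks were 0.03, 0.149 and 0.253. It was 49% with median-of-ratios size factors and with DESeq2, 49.4% with offsets on abundance and 49.1% with offsets within place classes, so the direction of the majority depended on the scaling. Gene-end peaks were over-represented among the lower ones (odds ratio 1.85, adjusted p = 2.91e-207, Fisher's exact test, two-sided).

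Averaged over both guides with weights, the inhibitor raised 18302 peaks and lowered 18534 (adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), 1362 and 927 of them by more than 2-fold. The higher share of these was 49.7% with TMM, 39.5% with library-size scaling and 30.1% with scaling from gene-end peaks. It was 48.9% with median-of-ratios size factors, 48.8% with offsets on abundance, 49.9% with offsets within place classes and 49.3% with DESeq2.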

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

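The share of the response at peaks outside gene ends, the thinning and the offsets within place classes were tests chosen only after the data were seen.

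The interaction test set apart 7680 peaks whose inhibitor effect was higher, and 5769 whose effect was lower, in gRNF4 than in gNT cells. Most of these shared a pattern, a smaller response in gRNF4 cells at regions such as SDHA, LPCAT1 and IGLL1. That majority follows in part from the selection, because the interaction contains the gNT effect with a minus sign. Peaks higher in the weighted mean effect had medians of 0.76 in gNT and 0.3 in gRNF4 cells, and lower ones -0.74 and -0.27. The exact permutation of guides gave p = 0.09 and 0.02 for these sets. A single library and depth were each argued against as the whole cause of the smaller response. Leaving out each gRNF4 inhibitor library in turn gave at most 4769 called peaks in gRNF4 cells. The gNT count was 8.3 times the gRNF4 count after thinning to the lowest total. Among peaks with high counts in the other 10 libraries the gRNF4 effect was 0.35 of the gNT effect, so the pattern was not limited to low-count peaks. All of these peaks held at least 73 counts in gRNF4 inhibitor replicate 3. Regions that closed there may be missing, so the peak set as a cause could not be tested for them. If a part of the gRNF4 cells had responded in full, all classes of peaks would show an equal share of the gNT change, but it was 15.5 ± 12.2% at strongly rising and 34.4 ± 9.5% at falling peaks, a difference of 18.9 points with an SD of 9.4 over 3 libraries, which passed its bound of 2 SD narrowly. Outside gene ends the difference was 19.9 points (SD 7.3), while moderately rising peaks (28.1 ± 45.4% over all places) did not separate from either class. These shares were computed with TMM scaling only, and their SD leaves out the spread of the gNT libraries. A part of the cells responding in full is therefore not excluded. A smaller response to the inhibitor in cells with the RNF4 guide may be biological, as a hypothesis found and tested on the same data. Slower growth of the gRNF4 cells, which would dilute methylation less, a lower effective dose, and a batch shared by a group could not be tested with these values.

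In a smaller pattern, 156 of the 7680 peaks were called higher in gRNF4 cells and 77 of the 5769, TSPEAR and AFAP1 among them, were called lower there, so that the difference did not come from a smaller response. Without gRNF4 inhibitor replicate 3, to which the peak set may be tied, 53 of the 156 rises (34%) and 33 of the 77 falls (42.9%) stayed called. A selection of peaks on that library predicts losses among the rises alone, and both directions lost calls, so for these peaks it cannot be told apart from the loss of a library.

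The gNT response was also set against a library-wide difference in signal between gene ends and other peaks, since the share of counts in gene-end peaks was higher in inhibitor-treated gNT cells. With each library's trend on abundance removed within each class of place, 41452 peaks were called in gNT cells, against 40607 before, so that trend was not the whole cause of the calls.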

How the results depend on the processing

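Chosen only after the results were seen were scaling from gene-end peaks, the limit to chromosomes 1 to 22 and X, the minimum of 73 counts, the removal of both gRNF4 inhibitor replicate 3 and gNT vehicle replicate 3, thinning, the offsets within place classes, and the odds ratios with other scalings or without gRNF4 inhibitor replicate 3. Of 401 values under alternatives, 347 kept their direction and side of the threshold, or for counts stayed within 1.5 times, and 0 reversed. Counts of peaks, which are most of these values, could only be labelled as kept or moved. The 0 therefore says nothing about the balance of calls. Between guides under inhibitor that balance turned, from 52.1% higher with TMM to 49% with median-of-ratios size factors. Every value was kept in this sense with median-of-ratios size factors, no filter, a stricter filter and offsets on abundance alone. So it was with thinning, chromosomes 1 to 22 and X, the replicate block and a distance of 2.5 kb. The block, whose numbers do not pair the libraries, called 17741 higher and 18907 lower in gNT and 2368 and 1816 in gRNF4 cells.

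At an adjusted p under 0.01, a stricter threshold by construction, calls were 13010 higher in gNT cells, 1035 higher and 579 lower in gRNF4 cells, 11733 and 10731 between guides under inhibitor, 2762 and 1745 for the interaction, and 11317 higher in the mean effect. The cause was not tested for the following. Library-size scaling gave 3528 lower for the interaction and 13 list calls by camera, against 14. Scaling from gene-end peaks gave 10521 higher in gNT cells, 1147 and 1177 in gRNF4 cells, 3 lower between guides under vehicle, 8556 lower under inhibitor, 2122 lower for the interaction and 9804 higher in the mean effect, with median differences of -0.44 (p = 0.045 by exact permutation, past the threshold) and 0.60 (p = 0.07, no longer past it). DESeq2 gave 3656 lower in gRNF4 cells, 3 and 24 between guides under vehicle, and r of 0.574, fits to the compared groups alone 1 and 38 under vehicle, and offsets within place classes 1 lower there. With at least 73 counts in every library, which leaves fewer peaks, gRNF4 cells had 1431 and 1336 calls. Without both libraries named above the interaction had 4548 and 3836, r was 0.684 and the median difference -0.49 (p = 0.025 by exact permutation, past the threshold).

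With 1 library left out in turn, which leaves fewer samples (and 1 gNT vehicle library in the extreme, assumed to vary like the other groups), calls ranged from 14239 to 21748 higher and 15044 to 21608 lower in gNT cells, 1282 to 2940 and 743 to 2308 in gRNF4 cells, 0 to 0 and 0 to 2 between guides under vehicle, 14569 to 18940 and 13170 to 18812 under inhibitor, 4408 to 8008 and 3166 to 6991 for the interaction, and 13362 to 21013 and 13313 to 20405 in the mean effect. The correlation ranged from 0.558 to 0.669 and the median differences from -0.53 to -0.41 and 0.46 to 0.53, where the exact permutation p was 0.05 without gRNF4 vehicle replicate 1 or 3 and 0.025 without gNT vehicle replicate 2. The odds ratio of gene-end peaks among peaks higher in gRNF4 cells was 0.92 without gRNF4 inhibitor replicate 3. Without that library 1779 of the 2980 higher and 1498 of the 2403 lower peaks in gRNF4 cells were called again. In gNT cells 19832 of 19890 and 20648 of 20717 were called again. That library is in neither group of the gNT comparison, so this is no check of the gNT calls. Depth limits peaks with low counts most, and thinning to 29621657 counts left every count within 1.5 times.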

Other observations

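The tests of low-count peaks and of the lowest count per library were chosen only after the results were seen.

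On chromosome 19 the guide effect under inhibitor had a median of -0.16, with -0.27 at gene-end and -0.10 at other peaks, and the interaction a median of -0.17. The MCM5, ADPRHL1 and DNAAF5 regions, 3 of the 10 with the largest rises in gRNF4 cells, rose by 4.94, 5.55 and 6.45 in gNT cells. The lowest adjusted p of any peak between guides under vehicle was 0.444, and that under inhibitor 3.5e-09.

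Every peak held at least 73 counts in gRNF4 inhibitor replicate 3, and that was the only library (1 of 11) with a lowest count above 0. Peaks called in, or filtered on, that library alone are a candidate explanation. It would raise low-count peaks in that group, and over the tenth of peaks with the lowest counts the median gRNF4 effect was 0.16 with that library and 0.07 without it. At 8 peaks the gRNF4 log2 fold change was over 2 with a gNT change within 1. They held 94 to 372 counts in that library and at most 45 in any other, and 0 of them passed the edgeR test (lowest adjusted p = 0.0652).

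For peaks called in gRNF4 cells, the 10 splits of 6 libraries are too few for a share under 0.05: the real split called 4063 peaks in a fit to these libraries and the highest of the others 0. The same holds for the guides under inhibitor, with 31433 and 0. For the mean effect over both guides, 21 of the 200 arrangements of the treatment within each guide were drawn, the real one included. Only 1, the real one, called as many as 36836 peaks, and 4 others called 6551 to 10611. With 21 drawn, the real one alone gives a share just under 0.05. The other arrangements were not run, so chance is not excluded.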
